A study of Mus musculus with 4 samples.

How the data were processed

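Spatial gene expression was measured on 4 coronal brain sections of male mice, 1 section for each combination of genotype and treatment. The mice carried human APOE3 or APOE4 in place of the mouse Apoe gene by targeted replacement, and they are named E3 and E4 below. Lipopolysaccharide (LPS) was injected into the abdomen at 5 mg/kg and the mice were killed 24 h later, per the series' stated design; the other treatment is given as NaCl (saline), and its volume and route are not stated. Per the labels' protocols, frozen right hemispheres were sectioned at 10 µm near Bregma -2.00 mm, fixed in methanol, stained, imaged and permeabilized for 18 min on 10x Genomics Visium slides, on which each spot of barcoded capture probes collects the RNA of the tissue above it. Libraries were sequenced on an Illumina NovaSeq instrument. The labels describe the tissue as brain and also hold an entry for non-neuronal brain cells, while neuronal transcripts were abundant in each section, so every deposited spot was treated as whole brain tissue.

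The deposited matrices hold raw UMI counts per gene and spot, with no normalization, for the spots kept by Space Ranger. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5.1b in Space Ranger 1.3.0, while per the file headers the matrices were written by Space Ranger 1.1.0, and the settings and annotation release are not stated. Each matrix was deposited as a pair of files with the same entries, and 1 copy was used. Neither spot positions nor images were among the files, so no map could be drawn and regions were called from expression alone. The feature list held 32285 mouse genes with 0 IDs from another species, and human APOE was not in it. Because 78 gene IDs shared their symbol with another ID, each ID was kept as a separate row in all fits. Positions of the 146 named genes were looked up by ID in GENCODE mouse release 21 (GRCm38), and all 146 were matched.

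UMIs were summed over all deposited spots of each section and tested with edgeR 4.0.16 (quasi-likelihood F test after TMM normalization, genes kept by filterByExpr, 14845 of 20971 genes with a UMI). The design was additive, with genotype and treatment, and left 1 residual degree of freedom. This fit compared 2 LPS with 2 NaCl sections and 2 E4 with 2 E3 sections, and its residual spread mixed animal differences with any difference between the genotypes' responses. The common dispersion was 0.0244 and the prior degrees of freedom 5.1. Adjusted p is Benjamini-Hochberg throughout, with a threshold of 0.05. In edgeR fits, ± gives the fitted log2 fold change divided by the square root of its F statistic. It serves as an approximate standard error and can be smaller than counting error for genes with few UMIs. In limma fits, ± gives the standard error. Within a genotype and for the difference between the genotypes' responses there was 1 section per group, so values are given without a test, with exact 95% intervals for a ratio of Poisson counts that cover counting error only. CPM are UMI counts scaled by the TMM-adjusted total of the section, and log2 ratios within a genotype used a prior count of 2 where they enter a list's median or a difference of responses. A count of 0 was given a floor of 3 UMIs per section.

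Lists of genes, 33 in number, were written from textbook knowledge, and each was tested against the other tested genes with camera in limma 3.58.1 (preset correlation 0.01, and again with an estimated correlation), adjusted over the 33 lists. The estimated correlation and its test rest on 1 residual degree of freedom, so a list could hardly pass there. A failure in that setting does not decide whether a list changed, and the choice of correlation is not settled by it. List medians of untested comparisons were placed among 10000 random lists matched on mean expression in 20 bins. Spots with at least 500 UMIs (9182 of 10371) were clustered jointly (2000 variable genes ranked and scaled within each section, 30 principal components, 15 neighbours, Leiden resolution 1.0), leaving out 539 genes that included the response lists and mitochondrial, haemoglobin, ribosomal protein and sex-linked genes. The 12 clusters are called regions and named by their leading genes, and 1 of them is not described by itself. The 8 regions with at least 20 spots in each section were fitted with edgeR as above, and the response of a region against the rest of its section was tested with limma on log2 CPM of region minus rest, for genes with at least 50 UMIs in the region. Shares of spots have exact (Clopper-Pearson) 95% intervals for counting error only.

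The named genes are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold for LPS that went the same way in both genotypes, 5 and 5 by the same rule for genotype (as values where none passed), the 8 and 8 with the largest difference of responses, the 4 members of each list with the largest LPS change, the 3 genes with the largest change in each region, the 10 with the smallest p for a region against the rest, and Apoe, Gfap, Aif1, Lcn2, Serpina3n, Xist and Ddx3y. Genes needed at least 100 UMIs in some section and a symbol that was not a clone name. Other members of a list that passed the threshold are named with their list, and any further gene is said to have been chosen after its values were seen. The comparisons, lists, naming rule and the alternatives below were fixed before the data were examined. The alternatives were RLE size factors, library totals only, no filter, a filter of 100 UMIs, DESeq2 1.42.0, limma-trend, a design with the tested factor alone, each section left out, spots with at least 500 UMIs, removal of mitochondrial and haemoglobin genes with Ttr and Enpp2, a common region composition, a prior count of 10, Leiden resolutions of 0.5 and 2.0, and thinning of regions to 48803 UMIs. A pair of alternatives was added after seeing the data (each section left out of the region fits, and a common floor of 10 CPM in the test of a region against the rest).

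The fits were tested on simulated data with the sections' depths and the estimated dispersion. With the additive design, edgeR recovered 64 of 100 genes changed 2-fold and 92 of 100 changed 4-fold by LPS. Among the genes left unchanged in the simulations for LPS and for genotype, it called 27 and 32. DESeq2 called 8 and 4 of them, and limma 24 and 38. For edgeR and limma these false calls were a larger share of all calls than the threshold of 0.05 allows. Camera with the preset correlation called the 1 raised list and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other, so this does not test the choice of correlation. Clustering used Python 3.11.15, scikit-learn 1.9.0 and leidenalg 0.10.2, and R was 4.3.3. With no group of 3 or more sections, splits of the sections into other groups were not counted.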

Results

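The data are Visium counts from 4 sections of mouse brain: E3 NaCl, E3 LPS, E4 NaCl and E4 LPS, with 1 section in each group and therefore no replicates within a group. Spots of a section are not replicates of an animal. The comparisons ask how the brain responded 24 h after a systemic dose of LPS, a bacterial endotoxin, whether the APOE genotypes differed, and whether they responded differently. In that order, the sections held 2702, 2615, 2805 and 2249 spots with 12023635, 9433017, 11420280 and 11793094 UMIs, 44670026 in all. Median UMIs per spot were 3305, 3050, 3376 and 4565, and median genes per spot were 1980.5, 1808, 1901 and 2453. Mitochondrially encoded genes took 8.29, 10.9, 12.2 and 9.82% of UMIs, so that E3 LPS and E4 NaCl had the higher shares. Haemoglobin genes took 0.0124, 0.0047, 0.0145 and 0.0021%, and Ttr, the choroid plexus carrier of thyroxine, took 1.09, 0.0699, 0.543 and 0.0896%. All 4 sections had the Y-linked Ddx3y, at 45.1, 42.0, 48.5 and 44.6 CPM, and 0, 2, 1 and 0 UMIs of Xist. Mouse Apoe, the locus replaced in these mice, was counted at 72.9, 105, 89.9 and 91.0 CPM, and its LPS log2 fold change of 0.27 ± 0.15 did not pass the test (adjusted p = 0.815). Because human APOE was not in the reference, it is not known which transcripts of the replaced locus these counts hold.

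Genes that rose after LPS encode, among others, the acute phase proteins Lcn2 and Saa3, the chemokines Ccl5 and Ccl12, the Fc receptors Fcgr4 and Fcgr3 and complement subunits, and 7 genes fell on the list for the choroid plexus, the epithelium that secretes cerebrospinal fluid. Lcn2, which encodes the iron-sequestering acute phase protein lipocalin 2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose from 0.485 to 141 CPM in E3 and from 0.996 to 292 CPM in E4, a log2 fold change of 8.17 ± 0.18 (adjusted p = 8.32e-05, 2 LPS against 2 NaCl sections). Saa3, for serum amyloid A3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose from 0 to 798 UMIs in E3, at least 352-fold against a floor of 3 UMIs in the section, and from 2 to 3572 UMIs in E4, a log2 ratio of 10.70 with a counting interval of 8.84 to 13.74. It passed the additive fit over the 4 sections (adjusted p = 1.05e-04). Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321) fell from 10585 to 705 CPM in E3 and from 5612 to 889.6 CPM in E4, a log2 fold change of -3.28 ± 0.30 (adjusted p = 0.0279). Opalin, a myelin protein of oligodendrocytes (ENSMUSG00000050121, chromosome 19, 41061710 to 41077113), fell from 27.8 to 5.66 CPM and from 35.6 to 4.80 CPM, a log2 fold change of -2.60 ± 0.22.

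In all, 50 of 14845 tested genes passed the threshold in edgeR, of which 35 rose and 15 fell, and 1113 had an unadjusted p under 0.05. Among the largest rises were the Fc receptor gene Fcgr4 (log2 fold change 5.54 ± 0.48), the chemokines Ccl5 (5.27 ± 0.63) and Ccl12 (4.02 ± 0.40), the lipid droplet protein gene Plin4 (4.03 ± 0.32), the cysteine protease inhibitor gene Ctla2a (4.37 ± 0.42), Tmem252 (4.47 ± 0.36) and Ch25h, which makes 25-hydroxycholesterol (3.80 ± 0.33). Fcgr4 had 2 UMIs in each NaCl section, so its log2 ratios of 5.33 in E3 and 5.89 in E4 carry counting intervals of 3.42 to 8.41 and 4.01 to 8.96. For Tmem252, with 3 UMIs in E3 NaCl, the E3 ratio was 5.36 with an interval of 3.77 to 7.66. Avp, the vasopressin hormone gene of the hypothalamus, rose by 5.37 ± 0.59 with 4.28, 69.8, 16.5 and 1399 CPM. At least 20 UMIs of Avp and Oxt together were found in 0, 7, 0 and 105 spots. Besides Ttr and Opalin, the largest falls were those of the potassium channel subunit gene Kcne2 (-3.23 ± 0.29), Ecrg4 (-2.74 ± 0.29), Sostdc1 (-2.62 ± 0.27), the folate receptor gene Folr1 (-2.58 ± 0.30), coagulation factor F5 (-2.37 ± 0.27), klotho (Kl, -2.00 ± 0.23), autotaxin (Enpp2, -1.96 ± 0.21) and osteoglycin (Ogn, -1.83 ± 0.20).

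**Figure D1:**
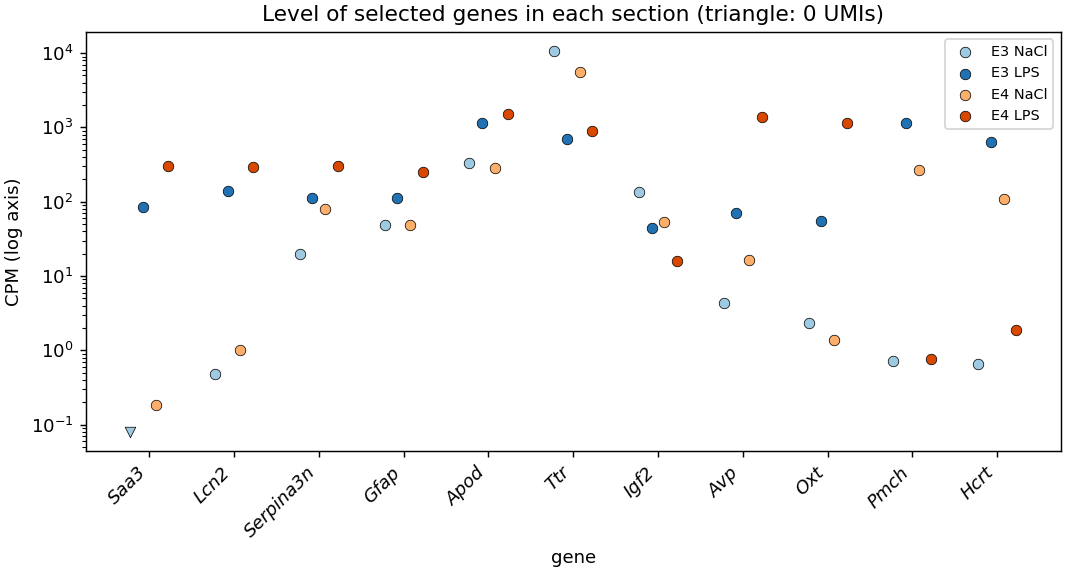
CPM of 11 genes on a log axis, 1 point per section (n = 1 per group, no error bars), with a triangle for 0 UMIs. Saa3, Lcn2 and Apod lie higher in both LPS sections than in both NaCl sections and Ttr and Igf2 lie lower, while Pmch and Hcrt are high in E3 LPS and E4 NaCl.

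In simulated data of the same depths, with 100 genes changed 2-fold and 100 changed 4-fold, edgeR also called 27 unchanged genes. Part of the 50 genes found here may therefore be false calls. With each section left out in turn and treatment alone in the design, the 50 genes kept their direction. They were chosen in part for moving alike in both genotypes, so this was largely fixed by the choice.

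The acute phase, glucocorticoid-responsive, activated microglia and complement lists had medians above 1, and passed only with the preset correlation. Of the 26 measured genes of the acute phase and NF-kB list, 5 rose (Saa3, Lcn2, Ch25h, and Lrg1 and Cebpd with 3.04 ± 0.27 and 1.81 ± 0.19), 0 fell and 21 were not called, and 17 rose when adjusted over the list alone; its median log2 fold change was 1.64, which does not depend on the exact value of Saa3 (adjusted p = 0.624 with an estimated correlation). Glucocorticoid-responsive genes had 5 of 23 risen (Lcn2, Plin4, Sgk1, Sult1a1 and Arrdc2), 0 fallen and 18 not called, 17 risen adjusted over the list alone, and a median of 1.33 (adjusted p = 0.624 with an estimated correlation). In the activated microglia list, 5 of 26 rose (Fcgr4, Ccl12, Ms4a6d at 3.21 ± 0.33, Cd52 at 2.37 ± 0.26 and Fcgr3 at 1.55 ± 0.16), 0 fell and 21 were not called, with 19 risen and 1 fallen adjusted over the list alone and a median of 1.29 (adjusted p = 0.624 with an estimated correlation). Complement had 4 of 15 risen (C5ar1 at 3.24 ± 0.39, C1qa at 1.54 ± 0.14, C4b at 1.31 ± 0.15 and C1qb at 1.24 ± 0.13), 0 fallen and 11 not called, 8 risen adjusted over the list alone, and a median of 1.12 (adjusted p = 0.624 with an estimated correlation). C1qa, a subunit of the initiator of the classical pathway, was at 64.4, 213, 83.3 and 212 CPM.

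Few genes of the astrocyte lists were called. In the pan-reactive astrocyte list, 2 of 12 rose (Lcn2 and Serpina3n), 0 fell and 10 were not called, 9 rose adjusted over the list alone, and the median was 1.53 (adjusted p = 0.624 with an estimated correlation). Serpina3n, a serine protease inhibitor gene (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), was at 19.96, 113, 80.0 and 305 CPM, and rose by 2.20 ± 0.17. Gfap, the astrocyte intermediate filament (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), was at 48.6, 113, 48.1 and 253 CPM and did not pass over all genes (1.81 ± 0.27, adjusted p = 0.0865). The A1 list had 1 of 11 risen (Fbln5, 1.46 ± 0.18), 0 fallen and 10 not called, 7 risen adjusted over the list alone, and a median of 1.20 (adjusted p = 0.624 with an estimated correlation). The A2 list had 0 of 9 risen or fallen, 2 risen adjusted over the list alone, and a median of 0.41 (adjusted p = 0.710 with an estimated correlation). Of the 15 disease-associated astrocyte genes, 2 rose (Serpina3n and C4b), 0 fell and 13 were not called, 4 rose adjusted over the list alone, and the median was 0.15 (adjusted p = 0.624 with an estimated correlation). Homeostatic astrocyte genes had 0 of 25 called, 1 risen and 1 fallen adjusted over the list alone, and a median of -0.07, with no call in camera (adjusted p = 0.816).

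Among further immune lists and homeostatic microglia genes, no gene was called over all genes. Interferon-stimulated genes, the antiviral program, had 0 of 28 called over all genes, 2 risen adjusted over the list alone, positive fitted values in all 28 and a median of 0.96 (adjusted p = 0.628 with an estimated correlation). Ifitm3, which blocks virus entry, was at 42.3, 89.0, 21.3 and 156 CPM (1.95 ± 0.40, adjusted p = 0.185). Antigen presentation genes had 0 of 18 called, 7 risen and 4 fallen adjusted over the list alone, a median of 0.57 and a mean of 0.16 (adjusted p = 0.721 with an estimated correlation). The 4 that fell so adjusted pulled the mean, and the class II gene H2-Aa was at 8.40, 1.28, 4.80 and 0.505 CPM (-2.92 ± 0.41, adjusted p = 0.0687). Homeostatic microglia genes had 0 of 15 called, 1 risen and 2 fallen adjusted over the list alone, and a median of -0.03, not called in camera (adjusted p = 0.695). With a common region composition, camera with the preset correlation called these genes lower (median -0.038, adjusted p = 0.0351). Among them the purinergic receptor gene P2ry12 was at 40.9, 16.8, 53.5 and 8.08 CPM (-1.98 ± 0.33, adjusted p = 0.108), and the microglial marker Aif1 was at 10.2, 18.7, 13.3 and 16.2 CPM (0.58 ± 0.22, adjusted p = 0.604). The neutrophil list had 4 measured genes, 0 called, 1 risen adjusted over the list alone and a median of 1.20 (adjusted p = 0.624 with an estimated correlation), with S100a8 at 2.26, 8.12, 0.272 and 9.34 CPM. Of monocyte and border macrophage genes, 0 of 10 were called, 2 rose adjusted over the list alone, and the median was 0.31, and of lymphocyte genes 0 of 3 were called, 0 adjusted over the list alone, with a median of -0.44; neither list was called in camera (adjusted p = 0.403 and 0.357).

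The choroid plexus list had the lowest median, next to that of red blood cell genes. With a common region composition the order was the opposite (-1.47 and -1.77). Of the 12 measured choroid plexus genes 7 fell (Ttr, Kcne2, Sostdc1, Folr1, Kl, Enpp2 and Clic6), 0 rose and 5 were not called, 11 fell adjusted over the list alone, and the median was -1.99 (adjusted p = 0.624 with an estimated correlation). The region led by Ttr and Ecrg4 took 1.88, 0.447, 0.929 and 0.770% of the sections' spots. Of 14 fibroblast and meningeal genes, 2 fell (Igf2 at -1.67 ± 0.12 and Igfbp2 at -1.72 ± 0.16, a growth factor and a binding protein), 0 rose and 12 were not called, 8 fell adjusted over the list alone, and the median was -0.73 (adjusted p = 0.624 with an estimated correlation). The region led by Ptgds and Igf2 took 3.43, 2.64, 2.26 and 2.65% of spots. The oligodendrocyte list split: Opalin fell, and Apod, a lipid-binding lipocalin (ENSMUSG00000022548, chromosome 16, 31296192 to 31314808), rose by 2.11 ± 0.18 with 329, 1160, 282 and 1499 CPM. The other 13 of its 15 genes were not called, 1 rose and 6 fell adjusted over the list alone, and the median was -0.61 (adjusted p = 0.628 with an estimated correlation). Red blood cell genes had 0 of 5 called, 4 fallen adjusted over the list alone and a median of -1.91 (adjusted p = 0.624 with an estimated correlation). Ependymal genes had 0 of 10 called, 0 adjusted over the list alone, and a median of -0.64 (adjusted p = 0.718 with an estimated correlation). With a common region composition the median was -0.16 and the camera call ended (adjusted p = 0.498). Mural cell genes had 0 of 12 called, 5 fallen adjusted over the list alone, and a median of -0.18 (adjusted p = 0.628 with an estimated correlation). Endothelial genes went both ways: Ly6a (2.10 ± 0.18) and the lipid transporter gene Mfsd2a (1.27 ± 0.15) rose, Pltp, for phospholipid transfer protein (-1.66 ± 0.13), fell and 15 of 18 were not called, with 7 risen and 5 fallen adjusted over the list alone, a median of 0.15 and no camera call (adjusted p = 0.403). Oligodendrocyte precursor genes had 0 of 10 called, 0 adjusted over the list alone, and a median of -0.12 (adjusted p = 0.549).

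Most metabolic lists had medians near 0 over both genotypes. The 23 cholesterol synthesis genes had 0 called, 7 fallen adjusted over the list alone, and a median of -0.24 (adjusted p = 0.624 with an estimated correlation), with Hmgcs1, an early enzyme of the pathway, at 175, 102, 173 and 103 CPM (-0.76 ± 0.12, adjusted p = 0.0895). Of 28 genes for lipid handling and fatty acid oxidation, 3 rose (Plin4, Ch25h and Apod), 0 fell and 25 were not called, 5 rose adjusted over the list alone, and the median was 0.11 (adjusted p = 0.624 with an estimated correlation). No gene was called by edgeR among 23 of glycolysis, 14 of the hypoxia response, 23 of the TCA cycle, 51 of nuclear-encoded oxidative phosphorylation and 13 mitochondrially encoded genes. Adjusted over the list alone, 1 rose in each of the first pair, and that gene was the glucose transporter Slc2a1 (0.70 ± 0.11, adjusted p over all genes = 0.0918), and 0 changed in the other 3 lists. Their medians were 0.01, -0.06, -0.08, -0.008 and 0.01, and camera called none of them (lowest adjusted p = 0.145). For mitochondrially encoded genes this median hides opposite responses, 0.46 in E3 and -0.39 in E4. Immediate early genes had 0 of 20 called, 2 fallen adjusted over the list alone, and a median of -0.33 (adjusted p = 0.624 with an estimated correlation), heat shock and unfolded protein genes 0 of 18 called, 0 adjusted over the list alone, and 0.16 (adjusted p = 0.694 with an estimated correlation), and synaptic genes 0 of 23 called, 0 adjusted over the list alone, and -0.03 (adjusted p = 0.695). By camera with the preset correlation 21 of 33 lists passed for LPS, and 0 did with an estimated correlation (lowest adjusted p = 0.624). With 1 residual degree of freedom the latter could hardly call any list, so it does not decide which lists changed. Each list named here with an estimated correlation had passed with the preset one.

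**Figure D2:**
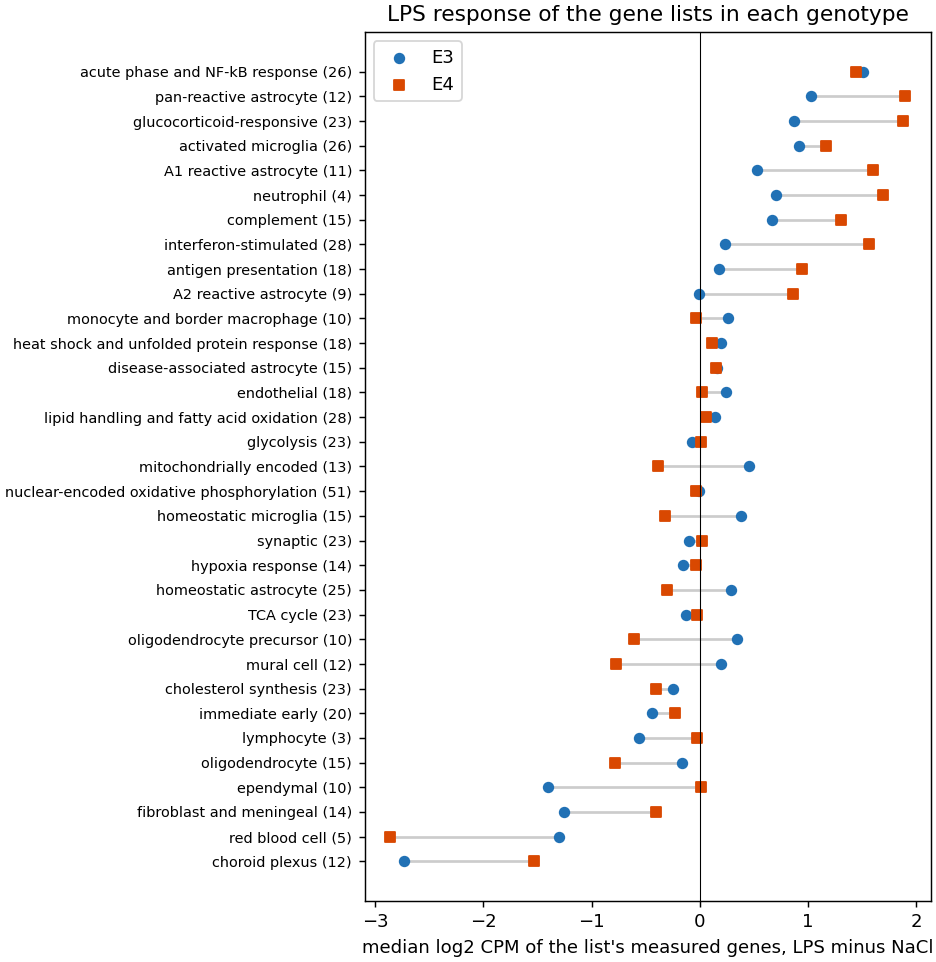
Median log2 CPM difference between LPS and NaCl over the measured genes of each list (number in brackets), as a circle for E3 and a square for E4 joined by a line, 1 section per group. Interferon-stimulated genes lie at 0.24 in E3 and 1.56 in E4, and the choroid plexus list lies at -2.74 and -1.53.

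The genotype comparison asked which genes differed between E4 and E3 over both treatments. Of 14 fibroblast and meningeal genes, 0 were higher in E4 in the NaCl sections and 4 in the LPS sections. The protease inhibitor gene Serpina3n was higher in E4 within each treatment. Igf2 was at 137, 44.2, 52.5 and 15.9 CPM (log2 fold change E4 against E3 -1.43 ± 0.12, adjusted p = 0.182), and fibronectin (Fn1) was at 51.6, 50.6, 20.6 and 17.5 CPM (-1.42 ± 0.14, adjusted p = 0.182). Serpina3n had a log2 fold change of 1.70 ± 0.17 (adjusted p = 0.182). None of these passed: edgeR called 0 genes for genotype, with 376 at an unadjusted p under 0.05, limma called 0 and DESeq2 6 (1 higher and 5 lower in E4). Further lower values in E4 were those of the collagen-binding proteoglycan Fmod (-2.09 ± 0.25), Ogn (-1.43 ± 0.20) and the growth factor Bmp6 (-1.26 ± 0.23). Higher values were those of Avp (3.35 ± 0.56), Saa3 (1.83 ± 0.18), Gbp6, an interferon-induced GTPase gene (1.54 ± 0.41), and Tmem252 (1.47 ± 0.33). Saa3 had almost no UMIs in the NaCl sections, so its value rests on the LPS sections.

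Of the lists, camera with the preset correlation placed 12 past the threshold for genotype, and 0 passed with an estimated correlation (adjusted p = 0.961 for 11 of them and 0.963 for interferon-stimulated genes). Here too the latter could hardly call a list with 1 residual degree of freedom. Fibroblast and meningeal genes were lower in E4 with a median of -0.87, and 10 of 14 fell adjusted over the list alone while 0 did over all genes. Also lower by camera were monocyte and border macrophage genes (median -0.996, 4 of 10 fallen adjusted over the list alone), mural cell genes (-0.36, 3 of 12), and endothelial (-0.29), choroid plexus (-0.50), red blood cell (-0.21) and heat shock genes (-0.14), each with 0 adjusted over the list alone. Higher in E4 by camera were pan-reactive astrocyte (0.30, 2 of 12 risen adjusted over the list alone), glucocorticoid-responsive (0.19, 1 of 23), interferon-stimulated (0.29, 0), A1 (0.27, 0) and mitochondrially encoded genes (0.22, 0). These medians run over both treatments, and several lists went opposite ways in the 2. In NaCl and in LPS sections, the medians E4 against E3 were -0.07 and 0.72 for pan-reactive astrocyte, -0.06 and 0.46 for glucocorticoid-responsive, -0.36 and 0.71 for interferon-stimulated, -0.22 and 0.65 for A1, 0.68 and -0.21 for mitochondrially encoded, 0.35 and -1.09 for red blood cell and -0.85 and 0.01 for choroid plexus genes. The red blood cell median turned positive, 0.11, with a common region composition, and its camera call ended (adjusted p = 0.294).

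Whether the genotypes responded differently to LPS could be described but not tested, since 1 section stood for each group. Over the 14845 tested genes the responses of E3 and E4 correlated weakly (Pearson r = 0.266, Spearman rho = 0.106, across genes, which are not independent replicates), and over the 50 genes past the threshold r was 0.962, a set chosen in part for moving alike. Of the 35 genes that rose, 20 had the larger response in E4, and of the 15 that fell, 4 fell further in E4. With a common region composition these counts were 22 and 8. Median responses were 2.43 in E3 and 2.15 in E4 for the genes that rose and -2.34 and -2.07 for those that fell.

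Interferon-stimulated genes differed most among the immune lists. The median difference of the 4 neutrophil genes was 0.99, but 0.62 with a common region composition, where that of interferon-stimulated genes was 1.18. The median response of interferon-stimulated genes was 0.24 in E3 and 1.56 in E4 on the log2 scale, 27 of 28 genes had the larger response in E4, and the median difference of 1.03 lay above all 10000 random lists. So did those of A1 astrocyte, glucocorticoid-responsive, immediate early, fibroblast and meningeal, choroid plexus and ependymal genes, so this placement does not single out interferon-stimulated genes. In the NaCl sections the interferon-stimulated median E4 against E3 was -0.36, and in the LPS sections it was 0.71. Irf7, a transcription factor of the interferon response, was at 1.54, 3.63, 0.815 and 9.59 CPM, and Ifi27l2a was at 10.4, 15.2, 2.72 and 14.4 CPM. The A1 list had medians of 0.53 in E3 and 1.60 in E4, and its member Gbp2, an interferon-induced GTPase gene, was at 5.98, 5.34, 3.80 and 41.4 CPM. The median over genes of the difference in response, E4 minus E3, was 0.59 for pan-reactive astrocyte, 0.53 for glucocorticoid-responsive, 0.53 for antigen presentation, 0.37 for complement, 0.29 for acute phase and 0.17 for activated microglia genes. Among single genes, Ccl5 was at 0.646, 5.34, 0.815 and 67.1 CPM, complement C3 at 2.42, 3.95, 0.362 and 14.5 CPM and Aqp1 at 10.8, 0.641, 4.35 and 3.45 CPM.

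The median response of homeostatic microglia genes was 0.38 in E3 and -0.32 in E4, that of homeostatic astrocyte genes 0.29 and -0.30, that of oligodendrocyte precursor genes 0.34 and -0.61, and that of mitochondrially encoded genes 0.46 and -0.39. Oligodendrocyte genes had medians of -0.16 and -0.79. All of these lists had the lower response in E4. In the same direction as interferon-stimulated genes, the medians of choroid plexus genes were -2.74 in E3 and -1.53 in E4, those of fibroblast and meningeal genes -1.25 and -0.41, and those of ependymal genes -1.41 and 0.01. With a common region composition the median over genes of the difference, E4 minus E3, moved from 0.86 to 0.33 for choroid plexus, 1.29 to 0.84 for ependymal, 0.63 to 0.43 for fibroblast and meningeal, -0.71 to -0.20 for oligodendrocyte, -0.77 to -0.39 for homeostatic microglia, -0.65 to -0.33 for homeostatic astrocyte, -0.89 to -0.49 for oligodendrocyte precursor, -0.65 to -0.34 for mural cell, 0.39 to 0.14 for immediate early, 0.17 to 0.10 for activated microglia, 0.05 to 0.11 for glycolysis and -0.82 to -0.54 for mitochondrially encoded genes. Several neuropeptide genes of the hypothalamus had large single differences: Pmch, for melanin-concentrating hormone, was at 0.727, 1160, 268 and 0.757 CPM, Hcrt, for orexin, at 0.646, 629, 110.5 and 1.85 CPM, and Oxt, for oxytocin, at 2.34, 55.7, 1.36 and 1138 CPM. Pmch and Hcrt were nearly absent in E3 NaCl and E4 LPS, where a section plane that missed their cells cannot be told apart from a response to LPS. The appetite peptide gene Pomc was at 4.28, 26.4, 14.0 and 3.96 CPM, and Gal, for galanin, at 1.29, 60.1, 27.3 and 20.4 CPM. A difference of responses between the genotypes is the same number as the contrast of E4 LPS and E3 NaCl with E3 LPS and E4 NaCl. The latter pair had mitochondrial shares of 10.9 and 12.2% and the former 9.82 and 8.29%, so whatever set these pairs of sections apart entered each of these values.

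**Figure D3:**
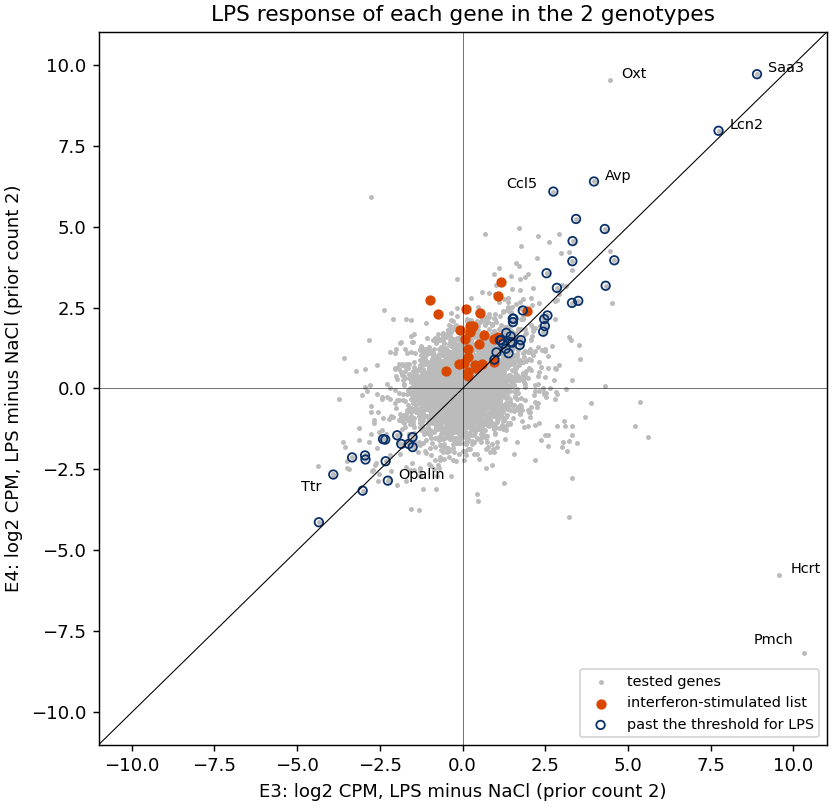
LPS response of 14845 tested genes in E4 against that in E3, each as log2 CPM of LPS minus NaCl with a prior count of 2, with a line of equal response. Open circles are the 50 genes past the threshold, and 27 of 28 interferon-stimulated genes (filled) lie above it.

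Regions asked where in the section the response took place, and whether the sections held the same tissue. Joint clustering gave 12 regions, which were compared with lists of markers. Highest in their regions were those of the thalamus in Prkcd/Tcf7l2, hypothalamus in Dlk1/Th, amygdala and piriform cortex in Ccn3/Lypd1, striatum in Penk/Adora2a, hippocampal CA1 in Cabp7/Spink8, meninges and large vessels in Ptgds/Igf2, and choroid plexus in Ttr/Ecrg4. Upper cortical layers and layer 4 scored alike in Lamp5/Kcnab3 (both 0.387). The sections did not hold the same shares of them. Dlk1/Th took 9.53% (8.38 to 10.8) of the clustered spots in E3 NaCl (exact 95% interval), against 17.7% (16.1 to 19.3) in E3 LPS, 18.2% (16.7 to 19.8) in E4 NaCl and 17.2% (15.6 to 18.9) in E4 LPS. Penk/Adora2a took 0.920, 3.85, 3.23 and 4.62% and Cabp7/Spink8 4.81, 0.760, 2.30 and 3.42%. These shares describe 1 section each and were not tested.

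**Figure D4:**
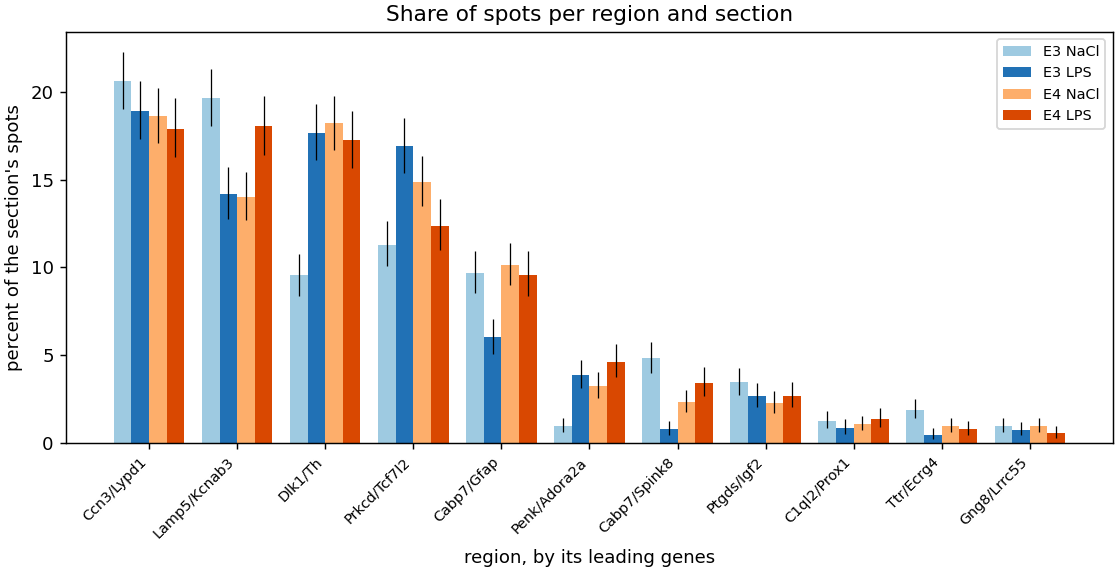
Percent of each section's clustered spots in each of 11 of the 12 regions, as bars from 0 with exact 95% binomial intervals (counting error only), 1 section per group. Penk/Adora2a is smallest in E3 NaCl at 0.92% and Cabp7/Spink8 smallest in E3 LPS at 0.76%.

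Of the genes called within the 8 tested regions, Lcn2, Saa3, Ctla2a and Apod rose in all 8, and Serpina3n rose in 7 of 8 (it was not called in Penk/Adora2a). Gfap rose in 6 of 8, with 2.24 ± 0.28 in Ccn3/Lypd1 and 1.71 ± 0.21 in Cabp7/Gfap, and P2ry12 fell in 6. Oxt, at 2.83, 143, 2.79 and 4502 CPM in Dlk1/Th, rose in 6 regions. Outside Dlk1/Th its counts may hold RNA of the same cells that reached other spots, as described at the end. In Ptgds/Igf2, Lcn2 was at 1.69, 1313, 4.47 and 2136 CPM, Saa3 at 0, 1016, 0 and 2158 CPM and the protease inhibitor gene Timp1 at 6.76, 79.0, 0 and 359 CPM. Acute phase genes had their highest regional median there, 2.66, with 8 of 12 risen, 0 fallen and 4 not called. Genes were filtered in each region by itself, and this list had from 6 measured genes in Penk/Adora2a to 19 in Ccn3/Lypd1. The regional medians therefore do not cover the same genes.

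Ccn3/Lypd1, Lamp5/Kcnab3, Dlk1/Th, Prkcd/Tcf7l2, Cabp7/Gfap, Penk/Adora2a and Ptgds/Igf2 had 96, 267, 60, 152, 51, 4 and 80 genes past the threshold in edgeR, and the 8 tested regions had 384 different genes in all. The counts moved with thinning and with single sections: with every region thinned to 48803 UMIs 36 genes passed, and without the E3 NaCl, E3 LPS, E4 NaCl or E4 LPS section (treatment alone in the design) 141, 636, 422 and 246 did. Per region, in the order above, a section left out gave 37 to 263, 55 to 389, 8 to 115, 19 to 248, 1 to 17, 13 to 44 and 10 to 127 genes.

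**Figure D5:**
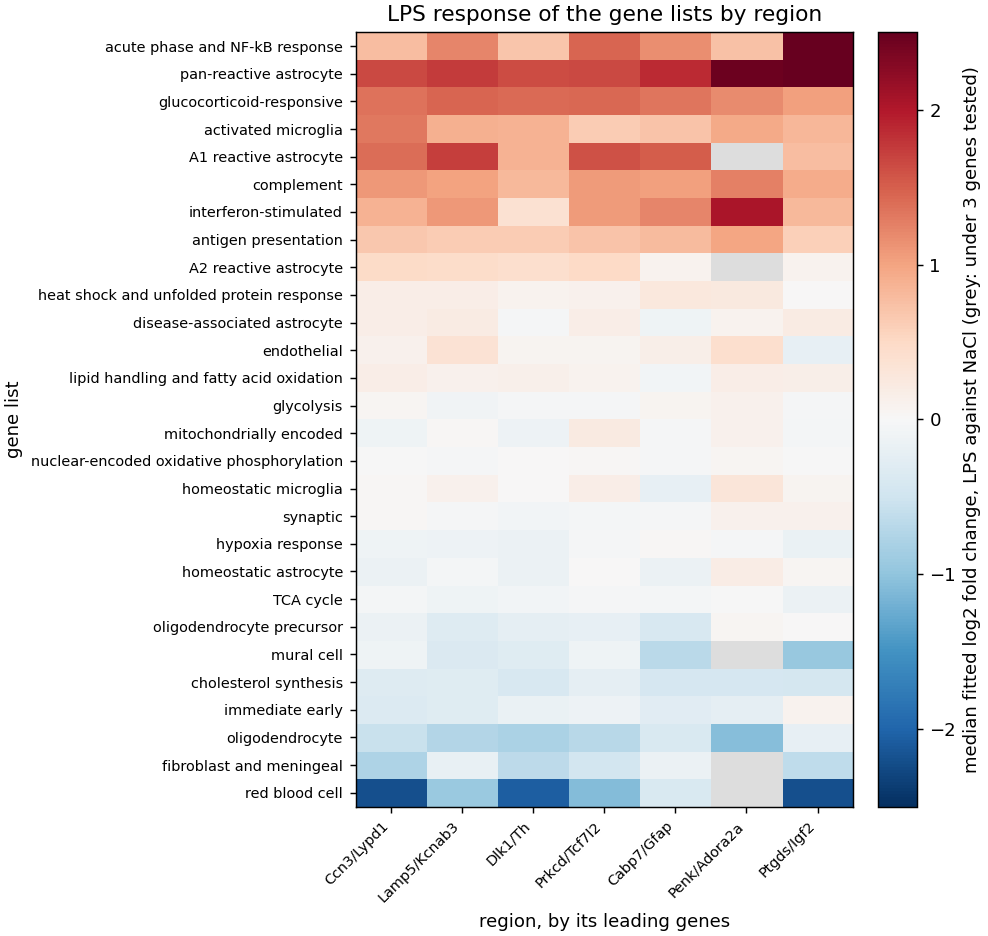
Median fitted log2 fold change of LPS against NaCl for each gene list in 7 of the 8 tested regions, on a colour scale from -2.5 to 2.5 (red higher with LPS, blue lower, values beyond the ends in the end colours, grey where fewer than 3 genes were tested). Pan-reactive astrocyte genes are positive in all 7, from 1.62 to 2.58, and oligodendrocyte genes negative in all 7. The measured genes of a list differ between regions.

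A gene's response in a region differed from that in the rest of its section for 20 of 40229 pairs of gene and region. Tiam2, an activator of the GTPase Rac, had a response higher by 2.48 ± 0.30 in Penk/Adora2a (adjusted p = 3.19e-07), and Ackr1, a chemokine-binding receptor of venules, one higher by 2.03 ± 0.37 in Ptgds/Igf2 (adjusted p = 0.000243). Oxt had a response lower by a log2 value of -3.46 ± 0.20 in Cabp7/Gfap (adjusted p = 1.03e-20). With a common floor of 10 CPM this value was -1.69 ± 0.30 (adjusted p = 0.000662). Of the 20, 13 were pairs of Saa3, Lcn2, Avp or Oxt with lower values in the region, genes with few UMIs in the NaCl sections. With the common floor, 9 pairs passed, 7 of them among the 20, and Ackr1 and the pairs of Saa3 and Lcn2 did not.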

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

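The test of tissue mixtures was written before its values were seen, while the tests of a single factor for all genes and of a property shared by a pair of sections were chosen only after the result was seen.

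Each list median or gene in this paragraph and the next was above 0 with LPS in one genotype and below 0 in the other, with 1 section per group, and the differences were not tested. Some lie next to 0, as the A2 median in E3 (-0.01), the ependymal and glycolysis medians in E4 (both 0.01) and the monocyte and border macrophage median in E4 (-0.04). With a common region composition the A2 medians (0.01 and 0.80) and those of monocyte and border macrophage genes (0.65 and 0.17) were positive in both genotypes. The median over genes of the difference in LPS response, E4 minus E3, was 0.998 for the A2 reactive astrocyte list, 1.29 for the ependymal list, 0.06 for the synaptic list and 0.05 for the glycolysis list. It was -0.65 for homeostatic astrocyte, -0.77 for homeostatic microglia, -0.82 for mitochondrially encoded, -0.65 for mural cell, -0.89 for oligodendrocyte precursor and -0.68 for monocyte and border macrophage genes. Scaling by library totals instead of TMM would add 0.11 to every gene.

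Among single genes the difference was -18.49 for Pmch, -15.34 for Hcrt, -7.11 for Fezf1, -5.77 for Gal, -4.84 for Irs4, -4.81 for Gabrq, -4.73 for Nts and -4.36 for Pomc, of which Pmch, Hcrt, Gal, Nts and Pomc encode neuropeptides made in the hypothalamus. Pmch and Hcrt were nearly absent in E3 NaCl and E4 LPS. For them a section plane that missed the cells expressing them cannot be told apart from a response to LPS, and this was not tested for the others. The difference was 4.52 for Slc9a4, 3.54 for Gbp2 and 3.30 for Dcn, a proteoglycan of fibroblasts. Growth hormone (Gh) had 31, 2, 0 and 125 UMIs in the order E3 NaCl, E3 LPS, E4 NaCl and E4 LPS, and its difference of 8.67 depends on the prior count and bounds nothing.

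Interferon-stimulated genes had the larger response in E4, by a median of 1.03. Different shares of regions in the sections do not alone account for it. Within the 8 tested regions the summed UMIs of the list had a median E4 minus E3 response of 1.31, positive in 8 of 8 regions (0.82 to 2.09). The smallest sum was 14 UMIs, in Penk/Adora2a of E3 NaCl. A different mixture of cells within a region was not tested and stays open. A larger response of all genes in the E4 animal by a single factor would also raise other responding genes. The 133 genes outside the list with a mean response of at least 1 (chosen without a test) had a median difference of 0.34. Of them, 77 had the larger response in E4. The bootstrap interval over genes, -0.01 to 0.57, lies below 1.03, but it treats genes as independent and holds no spread between animals. The list itself was not held to a mean response of at least 1, so a single factor is not excluded. A property shared by E3 LPS and E4 NaCl cannot be told apart from a response that depends on genotype, because the design sets this same pair against the other, and the lower mitochondrial share of the pair exceeded the higher of the others by 1.04 percentage points. A genotype effect, a difference between single animals, a different mixture of cells within regions and such a property may each account for the values. With 1 section per group none of them is decided.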

How the results depend on the processing

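The alternatives were planned, except the region fits with a section left out and the common floor of 10 CPM, which were chosen after seeing the data. For the 20 named LPS genes, 278 values under 14 settings gave 258 in the same direction and past the threshold, 20 in the same direction but not past it, and 0 reversed. The 50 genes called for LPS kept their direction under every setting that measured them. The 20 and the 50 genes were chosen in part for moving alike in both genotypes, so few reversals could occur. No paired analysis was possible because each group held 1 section, and the shared number 1 was given in the order of deposition and pairs no animals.

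Genes called for LPS numbered 195 with library totals only, 270 without a filter, 29 with at least 100 UMIs, 135 with DESeq2, 94 with treatment alone and 592 with a common region composition, which limma-trend tested; sections left out gave 111 to 420. Genes called for genotype numbered 7 with library totals only, 18 without a filter, 6 with DESeq2 and 76 with a common region composition, against 0 in the other settings. Lists past the threshold went from 21 to 0 for LPS and from 12 to 0 for genotype with an estimated correlation, which could hardly call a list with 1 residual degree of freedom. The correlation of the responses was 0.302 with a common region composition. Thinning of regions left 36 genes, sections left out 141 to 636, and the common floor 9 pairs of gene and region. Leiden resolutions of 0.5 and 2.0 gave 448 and 322 genes, of which 296 and 255 were among the 384. For each of these the cause was not tested.

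These list values reversed, and the cause was not tested; for LPS and genotype, lists called in neither setting are left out, whose medians near 0 changed sign too for some. With a common region composition the genotype medians were -0.027 for the disease-associated astrocyte list and 0.11 for the red blood cell list. The difference of responses was 0.075 with library totals and 0.085 with a common region composition for hypoxia, 0.072 and 0.097 for nuclear-encoded oxidative phosphorylation, and 0.074 and 0.031 for lipid handling genes. With a section left out, genotype stood alone in the design and 1 arm held a single treatment, so that genes that respond to LPS move by construction, and these values do not bear on the genotype difference. They were -1.16 to 7.37 for Avp, -7.78 to 13.79 for Saa3, -0.12 to 3.11 for Gbp6, -1.87 to 5.64 for Tmem252 and -0.22 to 0.31 for Apoe. Depth limits what the regions show, from 48803 UMIs in the smallest tested region to 4471044 in the largest.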

Other observations

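The test of the number of Ttr/Ecrg4 spots was chosen only after the result was seen, and the others here were written before their values were seen. The spots led by Ttr and Ecrg4, 45, 10, 23 and 16 in the order E3 NaCl, E3 LPS, E4 NaCl and E4 LPS, were too few to test, but LPS-responsive genes were counted there too. The genes of this paragraph were taken from those named for the whole section. Lcn2 was at 0, 176, 16.1 and 697 CPM in these spots, Saa3 at 0, 109.8, 0 and 655 CPM, Serpina3n at 18.6, 505, 53.7 and 1487 CPM and Apod at 268, 878, 300.4 and 1815 CPM. The summed interferon-stimulated genes were most abundant in Ptgds/Igf2 among the tested regions, at 1247, 1422, 523 and 2535 CPM.

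Choroid plexus genes were lower in the LPS sections. The median log2 fold change of the list moved from -1.99 only to -1.47 with the same region composition in every section. This cannot exclude fewer Ttr/Ecrg4 spots, since it does not remove RNA of these genes counted in other spots. In Ccn3/Lypd1, Ttr was at 5036, 248.5, 2127 and 432 CPM. Inside the Ttr/Ecrg4 spots Ttr was lower with LPS too, at 176590, 71880, 174760 and 36307 CPM. Less choroid plexus tissue within each spot would lower every gene by 1 factor. The log2 ratios of the 4 members with enough UMIs spanned 0.74 in E3 and 1.56 in E4. The span lay above the limits set beforehand in E4 and between them in E3. The rule asked for both genotypes, so the test cannot tell. In E4 LPS the extremes rest on 15 UMIs of Kl and 24 of Clic6. A loss of tissue and a lower expression in it cannot be told apart with 10 and 16 spots in the LPS sections, and both may contribute.

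Avp and Oxt were higher in the LPS sections, most of all in E4 LPS. A section plane through the cells that express them and a rise of their RNA with LPS cannot be told apart: the highest number of their UMIs in 1 spot was 18 in the NaCl sections, against 124 and 1654 in the LPS sections, which either would give. Avp was found in 84.5% of E4 LPS spots and 14.5% of E3 LPS spots, and its ratio to Oxt outside Dlk1/Th lay within 1.45-fold of that inside it in both LPS sections. The wide spread is therefore consistent with RNA from the same cells reaching other spots, and the regional values of Oxt and Avp in the rest of the section carry it. Both explanations of the higher totals stay open.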
